A study of Homo sapiens with 8 samples.

How the data were processed

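RNA was measured by sequencing in 8 libraries of CCRF-CEM, a human T-cell acute lymphoblastic leukaemia line, each infected with a vector for 1 short hairpin RNA and harvested 8 days later after puromycin selection, per the labels' protocols. The control hairpins were aimed at luciferase (shLuc) and at green fluorescent protein (shGFP). The other 6 hairpins were aimed at EZH2, EED and SUZ12, with 2 hairpins per target. Per the labels' protocols, column-purified total RNA was treated with DNase, ERCC spike-in RNA was added to a fixed mass of RNA, libraries were made with the NEBNext Ultra RNA kit, and sequencing was single-read on a HiSeq 2000. Each hairpin had 1 library, so each library came from its own infection and no hairpin was repeated. Whether the infections started from separate cultures is not stated. The spread within a group mixes differences between hairpins with differences between libraries, and p-values measure only the spread between these samples.

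Per the submitters' processing notes, STAR 2.3.1z4, featureCounts and DESeq were used with the hg19 genome. The gene annotation, the strand setting and any filter on reads are not given in the sources used here, so genes that overlap on opposite strands cannot be told apart. The deposited table held 1 normalized value per gene and library, a signal that the authors made from read counts per gene. It had 56730 rows, of which 92 were ERCC spike-ins and 56638 were genes. In each library every value was a whole number of reads divided by 1 factor (100% of values whole within a tolerance of 0.01 reads), so the reads could be recovered. The factors were equal to size factors recomputed by the median of ratios over all rows, spike-ins included. Row names that a spreadsheet had turned into dates (28 rows) and rows with a repeated name (4 rows) were named nowhere in the results. All 8 libraries had a column of values that was used, and whether the table held further columns was not checked.

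Recovered gene reads ranged from 29106418 to 47823258 per library, and ERCC reads made up 5.21% to 12.9% of all reads. Averaged over genes, counting error was small beside the differences between libraries: chi-square per gene between the libraries of 1 group ranged from 39.4 to 104, where counting error alone gives about 1. That mean is dominated by abundant genes and does not cover genes near the minimum value. The 2 libraries of each group were counted as separate samples, which these values cannot show. Near-identical genes (HLA class I, histone, ribosomal protein and heat shock genes with pseudogene copies) can share reads, and their values are uncertain for that reason.

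The design was fixed before the data were examined and assumed raw counts with edgeR as the test. Because the deposited values were normalized, the fallback written in the same design was used: limma 3.58.1 in R 4.3.3 with an intensity trend, on log2(value + 1), for genes with a value of at least 10 in at least 2 libraries (17239 genes). Fold changes are on the log2(value + 1) scale, which understates changes of low genes. The 6 knockdown libraries were set against the 2 controls in a fit with 2 arms. The targets were set against control and against each other as contrasts of a fit with 4 groups, all 8 libraries sharing 1 estimate of the spread. The threshold was a Benjamini-Hochberg adjusted p of 0.05. edgeR 4.0.16 (quasi-likelihood, TMM factors) was run on the recovered reads as an added alternative and called 0 genes in each of the 7 comparisons, and DESeq2 1.42.0 was run as a planned one.

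Written before the data were examined were 44 gene lists with 1176 entries, each of which had a row. They were tested with camera on log2(value + 1) in place of log2 CPM, with a preset correlation of 0.01, and again with an estimated correlation and with fry. Members were also adjusted over the list alone. That adjustment does not extend across the 44 lists or the 7 comparisons, so some members can pass by chance. CRIP2 and TRAP1 were named because the study is known to have followed them up from these samples, so their values here are not independent evidence.

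The rule for named genes took the 3 targeted genes, CRIP2 and TRAP1, then the largest changes past the threshold in each comparison and up to 4 members past the threshold per list, or the 2 most highly expressed members of a list with none. Since no gene passed the threshold, other genes were chosen after their values were seen: by smallest p among the genes with all 6 knockdown libraries on 1 side of both controls, by smallest p in each contrast of targets, or by passing the threshold over their list alone.

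Agreement between targets was measured by the correlation and covariance across genes of log2 fold changes against the shared controls, beside 20 simulations of unchanged groups. Resemblance of the hairpins for 1 target was set against all 15 ways to pair the 6 knockdown libraries. Data were simulated for the comparison of 6 with 2 libraries, with 200 of 17239 genes changed. The changed genes were drawn only from those with a mean of at least 100 normalized reads. On these data limma called 52.4% of 2-fold and 97.4% of 4-fold changes with a mean of 10.2 false calls. DESeq2, run on 2 such simulations, gave a mean of 34 false calls. With changes implanted in the real libraries, in genes with the same minimum mean, limma called 41.3% of 2-fold and 96.1% of 4-fold changes. For shSUZ12 against control, the simulated data gave a mean of 6 false calls with limma and of 30 with DESeq2.

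Alternatives were DESeq2, edgeR with other factors, factors from the ERCC reads, no filter on low values, another pseudocount, and leaving out each library. Transcript length, GC content and gene type came from GENCODE release 29, matched by symbol for 14505 of the tested genes (84.1%). That annotation belongs to another genome build than hg19, so no coordinates are given.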

Results

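The data were RNA-seq profiles of CCRF-CEM cells carrying hairpins against the core of polycomb repressive complex 2 (PRC2), which places the repressive methyl marks on lysine 27 of histone H3. EZH2 is its catalytic subunit, and EED and SUZ12 are subunits that the catalytic activity requires. There were 2 control libraries (shLuc and shGFP) and 2 libraries for each of the 3 targets, named by target and hairpin number, so that shSUZ12.3 is hairpin 3 against SUZ12. Gene reads numbered 35324924 in shLuc, 44187678 in shGFP, 36363655 and 46297359 in the shEZH2 libraries, 47823258 and 33503502 in the shEED libraries, and 29106418 and 31067096 in the shSUZ12 libraries. Values are normalized reads, and errors are standard deviations between libraries unless given as a standard error (SE).

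The first question was whether each hairpin lowered its target. EZH2 measured 3493 and 3661 normalized reads in the shEZH2 libraries (mean 3577 ± 119, SD, n = 2), 52.8% of the control mean, and 5868 to 8433 in the other 6 libraries. EED measured 1014 and 1085 in the shEED libraries (mean 1050 ± 50.6, SD, n = 2), 62.5% of the control mean, and 1470 to 2375 in the other 6. SUZ12 measured 3526 and 3387 in the shSUZ12 libraries (mean 3457 ± 98.6, SD, n = 2), 72.5% of the control mean, and 3882 to 6709 in the other 6. For each target both of its own libraries lay below the other 6, with an exact one-sided permutation p of 0.0357, the smallest that 2 libraries against 6 can give. That order held for the deposited scaling but not for factors from the ERCC reads. On those factors shEZH2.4, shEED.5 and shSUZ12.2 each lay above shLuc in their own target. The log2 fold change of EZH2 in the shEZH2 libraries against control was then -0.51. Against control alone, the log2 fold change was -0.91 for EZH2 (SE 0.21), -0.67 for EED (SE 0.23) and -0.44 for SUZ12 (SE 0.26). Adjusted over the 3 targets, the limma p was 0.00312 for EZH2, 0.0188 for EED and 0.116 for SUZ12, so the fall of SUZ12 against the 2 controls alone did not exceed the spread between libraries.

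**Figure D1:**
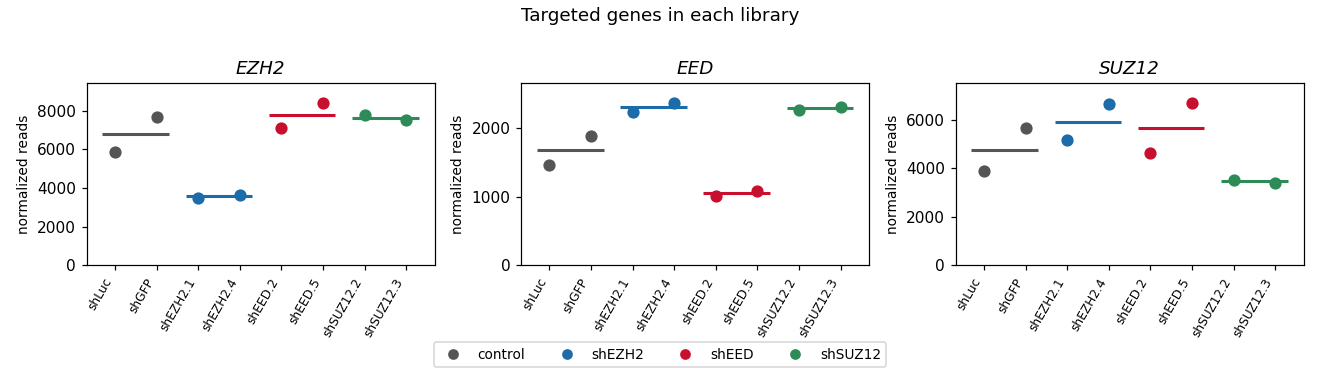
Normalized reads (vertical axis, from 0) of EZH2, EED and SUZ12 in each of the 8 libraries (horizontal axis); points are libraries and bars are group means. In each panel the libraries of the matching hairpins are the lowest: 3493 and 3661 for EZH2, 1014 and 1085 for EED, and 3526 and 3387 for SUZ12.

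The main comparison asked which genes differed between the 6 knockdown libraries and the 2 controls. TRAP1, a mitochondrial HSP90 chaperone that counters opening of the permeability transition pore, measured 3739 ± 845 (SD, n = 2) in controls and 5496 ± 561 (SD, n = 6) after knockdown, a log2 fold change of 0.57 (SE 0.17). CRIP2, a LIM domain protein, measured 8.91 ± 3.44 (SD, n = 2) in controls and 31.2 ± 19.2 (SD, n = 6) after knockdown, a log2 fold change of 1.55 (SE 0.58). Both genes were higher in 6 of 6 knockdown libraries than in both controls, yet the limma adjusted p was 0.948 for each. The study followed up these 2 genes from these samples, so their direction here is not independent evidence. Without shLuc the log2 fold changes were 0.34 for TRAP1 and 1.19 for CRIP2 (limma adjusted p 1.00 for each), and without shGFP 0.80 and 1.91 (0.279 and 0.446).

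Among the genes with all 6 knockdown libraries above both controls, those with the smallest p were TRMT6, which encodes a subunit of a tRNA methyltransferase, and NDRG4. TRMT6 measured 2160 ± 33.4 (SD, n = 2) in controls and 3345 ± 283 (SD, n = 6) after knockdown, a log2 fold change of 0.63 (SE 0.16), and NDRG4 measured 13.6 ± 2.49 and 39.2 ± 7.51, a log2 fold change of 1.45 (SE 0.38). PRPF4B, a kinase of the splicing machinery, CLTC, the clathrin heavy chain, and NFYA, a subunit of a CCAAT-binding factor, had log2 fold changes of 0.63, 0.58 and 0.63. Also in this set were EPB41L1, CEBPZ, IKBKG, UBTD2, IWS1 and PHLDB1, from 0.45 for IWS1 to 1.37 for EPB41L1. Below both controls in all 6 knockdown libraries lay NT5M, a mitochondrial nucleotidase, with 2278 ± 451 (SD, n = 2) in controls and 1095 ± 369 (SD, n = 6) after knockdown, a log2 fold change of -1.12 (SE 0.31). LMO2, a LIM domain partner of TAL1 and an oncogene in this leukaemia, measured 1149 ± 198 and 646 ± 158, a log2 fold change of -0.85 (SE 0.24), and CHI3L2, a chitinase-like protein, 39604 ± 11163 and 18342 ± 7874, a log2 fold change of -1.20 (SE 0.36). FAM117A, TSPAN7, BIN2, SERPINI1, PLAC1, C5orf56, HHLA3, CCL25 and TRAV22, a T-cell receptor alpha variable segment, were also below, from -2.86 for CCL25 to -0.57 for BIN2. The limma adjusted p was 0.948 for each of these genes, which were chosen after their values were seen.

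**Figure D2:**
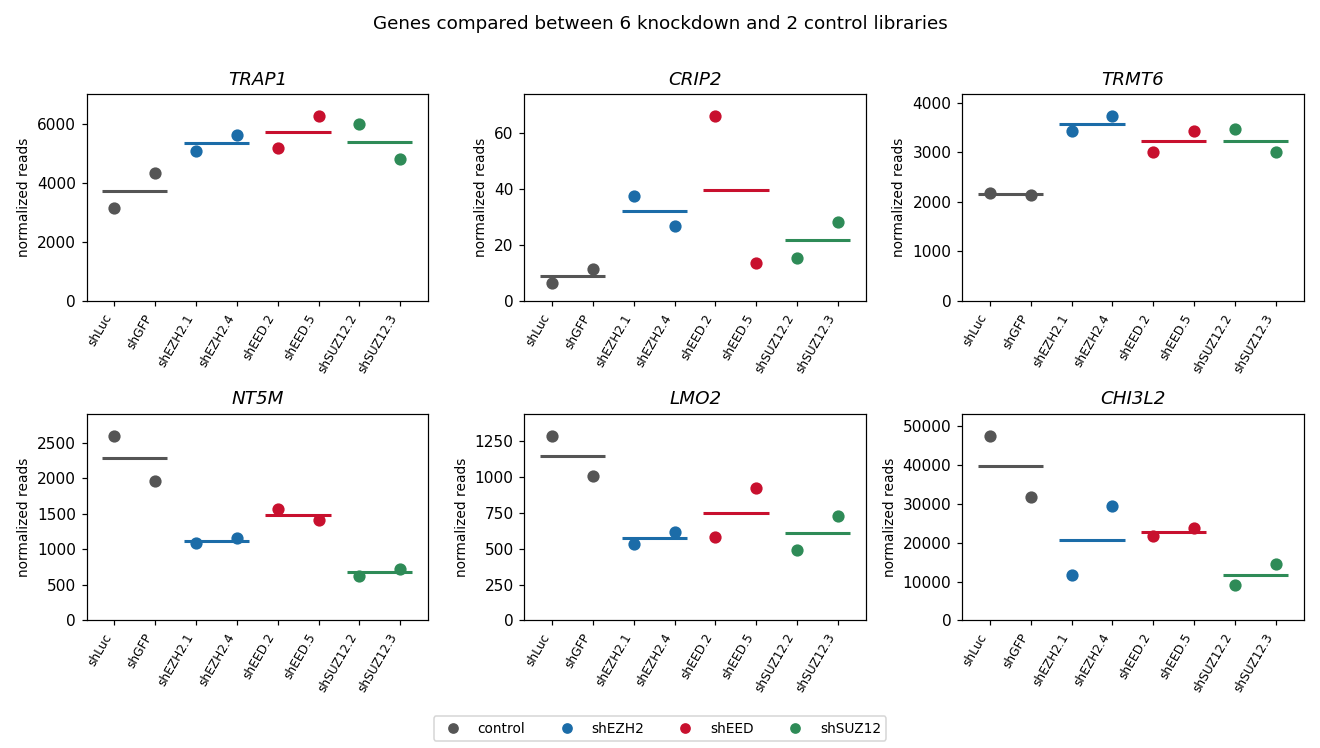
Normalized reads (vertical axes, from 0) of TRAP1, CRIP2, TRMT6, NT5M, LMO2 and CHI3L2 in each of the 8 libraries (horizontal axis); points are libraries and bars are group means. The 6 knockdown libraries lie above both controls for TRAP1, CRIP2 and TRMT6 and below both for NT5M, LMO2 and CHI3L2, and none of these genes passed the threshold in limma when adjusted over all genes.

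No gene of the 17239 tested passed an adjusted p of 0.05 in limma, with 508 at an unadjusted p under 0.05 where chance alone would give 862. edgeR on the recovered reads called 0 genes (537 unadjusted) and DESeq2 called 0 (656 unadjusted). Genes with all 6 knockdown libraries on 1 side of both controls numbered 852, 363 above and 489 below, or 4.94% of those tested, where chance gives 7.14%. Without shGFP, limma called 5 genes: MYO18A and EDC4 higher and HIST1H1D, HIST1H1B and RNA18S5 lower, each set apart by its value in shLuc alone. HIST1H1D measured 1856 in shLuc and 24.1 to 82.9 in the other 7 libraries.

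The gene lists asked whether known groups moved together between knockdown and control. Of 44 lists, 11 passed camera with the preset correlation, and none did with an estimated correlation (smallest adjusted p = 0.711 with an estimated correlation) or by fry (smallest adjusted p 0.671). At an unadjusted p under 0.05, the estimated correlation left 1 list and fry 2. None of the 827 tested members passed over all genes. Adjusted over the list alone, 1 did: LMO2 fell (adjusted p 0.0465 in limma, log2 fold change -0.85), and that call was lost without any 1 of the libraries except shEED.5, with an adjusted p of up to 0.371 without shLuc. With factors from the ERCC reads its adjusted p over the list was 0.905, at a log2 fold change of -0.62, and 3 other members passed. Lists were not adjusted for one another, so the 1 list of 44 with a passing member in the main test may be chance. The number of members passing over the list alone was 0 without shLuc, shEZH2.1, shSUZ12.2 or shSUZ12.3, 5 without shEED.2 and 26 without shGFP. The number of lists passing camera was 5 without shLuc or shEED.5 and 7 without shGFP or shSUZ12.3. With factors from the ERCC reads the median log2 fold change of all genes moved to 0.22, and the difference of each of the 11 lists from the other genes kept its direction. The camera adjusted p was then 0.517 for ribosomal proteins and oxidative phosphorylation, 0.294 for mitochondrially encoded genes, 0.161 for mitochondrial chaperones and 0.0877 for the modifier list.

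Antigen presentation genes were lower on average: the MHC class I list had a mean log2 fold change of -0.34 over 18 members, 14 of them lower (camera adjusted p 0.00929, and adjusted p = 0.711 with an estimated correlation). B2M, the class I light chain, had a log2 fold change of -0.29 (0.03 without shLuc), and none of the members passed the test, also when adjusted over the list alone. The interferon-stimulated list had a mean of -0.29, with 30 of 38 members lower (camera adjusted p 0.0125, and adjusted p = 0.711 with an estimated correlation). The NK and cytotoxic list, whose members include the protease gene CTSW (log2 fold change -0.75), had a mean of -0.60 over 12 members, 11 of them lower (camera adjusted p 0.0435, and adjusted p = 0.711 with an estimated correlation). Over the 3 lists, 0 members passed over all genes and 0 adjusted over the list alone. The MHC class I call was lost without shLuc (camera adjusted p 0.113), where the difference from the other genes went from -0.29 to -0.15, and the interferon call without shGFP (0.423). The NK call was lost without shLuc (0.336, difference from -0.55 to -0.31), shGFP (0.119), shEED.5 (0.117) or shSUZ12.3 (0.130).

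Of the 11 lists, 4 were higher on average. Targets of MYC in ribosome biogenesis and nucleotide synthesis had a mean log2 fold change of 0.16, with 22 of 30 members higher (camera adjusted p 0.00261, and adjusted p = 0.711 with an estimated correlation), including NCL, the nucleolar protein nucleolin, at 0.32. Cell cycle and mitosis genes had a mean of 0.16, with 22 of 30 higher (camera adjusted p 0.00261, and adjusted p = 0.711 with an estimated correlation), including the spindle factor TPX2 at 0.30. Mitochondrial chaperones and permeability transition genes, a list that holds TRAP1, had a mean of 0.11, with 16 of 23 higher (camera adjusted p 0.0452, and adjusted p = 0.711 with an estimated correlation), including the chaperonin HSPD1 at 0.34. Because TRAP1 was taken from the study, the direction of that list is not independent evidence. Genes for H3K27 and H3K4 modifiers had a mean of 0.19, with 14 of 16 higher (camera adjusted p 0.0303, and adjusted p = 0.711 with an estimated correlation), including the demethylase KDM5C at 0.33 (-0.11 without shLuc). In these 4 lists 0 members passed over all genes and 0 adjusted over the list alone. The MYC target call was lost without shGFP (camera adjusted p 0.0949) and the cell cycle call without shLuc (0.101). The chaperone call was lost without shGFP (0.423), shEED.2 (0.102), shSUZ12.2 (0.0851), shEED.5 (0.0610) or shEZH2.4 (0.0506). The modifier list differed from the other genes by 0.24, by 0.0198 without shLuc and by 0.47 without shGFP. The modifier call was lost without shLuc (0.842), shSUZ12.3 (0.110), shEED.5 (0.0651), shSUZ12.2 (0.0558) or shEZH2.4 (0.0506).

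Histone genes listed as lacking poly(A) tails were lower after knockdown, and this followed shLuc. Their mean log2 fold change was -1.02, with 15 of 16 members lower (camera adjusted p 1.7e-04, and adjusted p = 0.711 with an estimated correlation). The list mean in shLuc was 1.93 above the mean of the 8 libraries on the log2 scale, while shGFP was -0.40 and the knockdown libraries -0.48 to -0.08. Ribosomal protein genes (mean -0.14, 41 of 46 lower, camera adjusted p 0.0303), genes encoded by the mitochondrial genome (mean -0.24, 13 of 13 lower, 0.0310) and oxidative phosphorylation genes (mean -0.14, 36 of 42 lower, 0.0435) were also lower. With an estimated correlation their adjusted p was 0.830, 0.711 and 0.786. Without shLuc all 4 lists changed direction: the difference from the other genes was 0.21 for histone genes, 0.15 for ribosomal protein genes, 0.12 for mitochondrial genes and 0.21 for oxidative phosphorylation, the last with a camera adjusted p of 1.9e-04. Of the 4 lists, 0 members passed over all genes and 0 adjusted over the list alone. The last 3 calls were also lost without shEZH2.4 (camera adjusted p 0.277, 0.102 and 0.107) or shEED.5 (0.0610, 0.117 and 0.0610). Those for ribosomal proteins and oxidative phosphorylation were lost without shSUZ12.2 (0.114 and 0.0718) or shSUZ12.3 (0.0625 and 0.172), and the mitochondrial one without shEED.2 (0.0883).

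**Figure D3:**
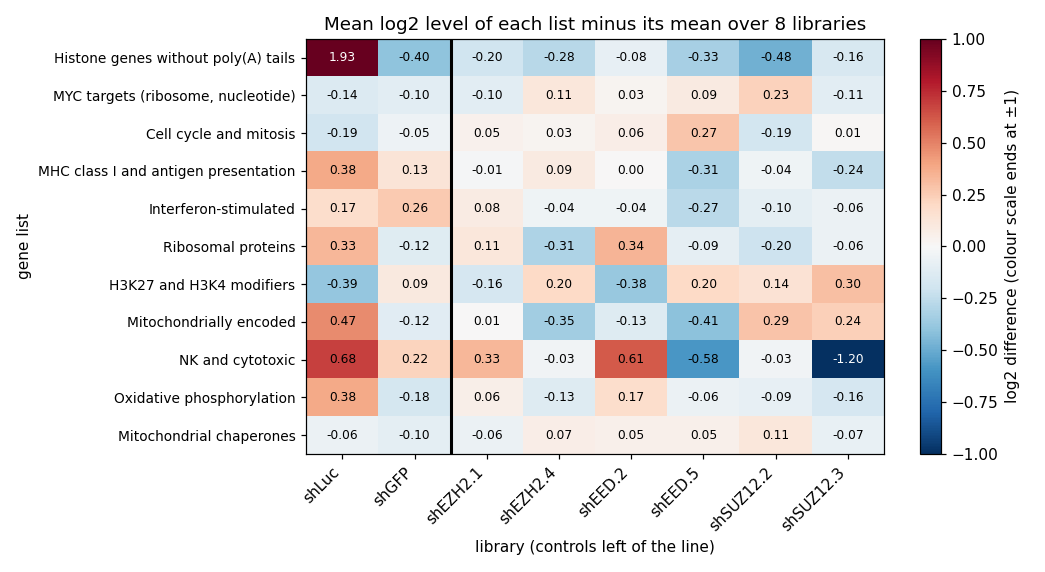
Mean log2 level of each of the 11 lists that passed camera with the preset correlation (vertical axis) in each library (horizontal axis), minus the list's mean over the 8 libraries; colours end at -1 and 1 and each cell prints its value. The histone list stands at 1.93 in shLuc and between -0.48 and -0.08 in the other 7 libraries, and none of the 11 lists passed with an estimated correlation.

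Lists closest to the function of PRC2 did not pass the test. PRC2 subunits had a mean log2 fold change of 0.08 over 13 members (camera adjusted p 0.429) and PRC1 subunits 0.05 over 22 (0.423). Of the 39 HOX genes on the list, which set positional identity and are classic targets of the complex, 7 were expressed enough to test, with a mean of -0.17 and 6 of 7 lower (0.545). Without shGFP the HOX difference from the other genes was 0.03. Of 97 developmental regulators bound by PRC2 in embryonic stem cells, 24 were tested, with a mean of -0.14 and 16 lower (0.468), among them PAX6 (-0.07) and IRX3 (-0.06). Cyclin-dependent kinase inhibitors had a mean of -0.16 over 7 members (0.839), the BCL2 family 0.06 over 17 (0.935), NOTCH1 targets 0.09 over 17 (0.609) and T-cell identity genes -0.10 over 32 (0.563). In these 8 lists 0 members passed over all genes and 0 adjusted over the list alone. Markers of other cell types did not pass either, with means of -0.32 for myeloid genes (0.236), -0.38 for B-cell genes (0.0771), -0.48 for erythroid and megakaryocyte genes (0.144), -0.42 for epithelial and embryonic kidney genes (0.0792) and 0.17 for fibroblast and stromal genes (0.563). For p53 targets the mean (0.01) differed in sign from the median (-0.03) and from the direction of camera (adjusted p 0.992).

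The EZH2 hairpins alone were then set against control. SCG2, a neuroendocrine secretory protein of the neuronal list, measured 1409 ± 56.7 (SD, n = 2) in the shEZH2 libraries and 431 ± 217 (SD, n = 2) in controls, a log2 fold change of 1.80 (SE 0.49). DLGAP3, a postsynaptic scaffold protein, measured 282 ± 70.6 and 83.1 ± 6.19, a log2 fold change of 1.73 (SE 0.39), and TRMT6 had a log2 fold change of 0.73 (SE 0.21). Lowest by p were ALDH1A2, which makes retinoic acid, at 11530 ± 1369 and 22498 ± 3828 (log2 fold change -0.96, SE 0.20), EZH2 itself, and NT5M (-1.01, SE 0.24). limma called 0 genes over all 17239 (198 at an unadjusted p under 0.05), edgeR 0 (212) and DESeq2 0 (240). Adjusted over the list alone, 2 members passed: EZH2 fell (limma adjusted p 0.0135) and SCG2 rose (0.0356). Lists were not adjusted for one another, and 2 of 44 with a passing member may be chance, although EZH2 is the targeted gene. The EZH2 call was lost without shGFP, shEZH2.1 or shEZH2.4 (limma adjusted p up to 0.158) and the SCG2 call without shLuc or shEZH2.4 (up to 0.563). The number passing was 1 without shLuc, 4 without shEZH2.1, shEED.2 or shEED.5, 10 without shEZH2.4 and 19 without shGFP. On ERCC factors 0 members passed over the list alone (adjusted p 0.666 for EZH2 and 0.0528 for SCG2). The log2 fold changes were then -0.51 for EZH2 and 2.20 for SCG2, with the median of all genes moved to 0.40.

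After EED knockdown the clearest difference was in BNIP3, a mitochondrial protein of the BCL2 family that is induced by hypoxia. BNIP3 measured 1310 ± 150 (SD, n = 2) in the shEED libraries and 312 ± 34.7 (SD, n = 2) in controls, a log2 fold change of 2.06 (SE 0.35). Adjusted over the list alone it rose (limma adjusted p 0.00109), and it passed without each library in turn, with an adjusted p of up to 0.0248. PFKFB4, a regulator of glycolysis, measured 357 ± 10.2 and 105 ± 5.06 (log2 fold change 1.76, SE 0.38), and NDRG4 had a log2 fold change of 1.64 (SE 0.50). SLC32A1, a vesicular transporter of inhibitory transmitters, had -1.29 (SE 0.33), CTNND1, which encodes the catenin p120, -1.27 (SE 0.37), and ANXA9 -1.38 (SE 0.41). Over all genes limma called 0 (310 at an unadjusted p under 0.05) and edgeR 0 (311), while DESeq2 called 1, BNIP3, with an adjusted p of 9.3e-05 (356 unadjusted). Without shGFP limma called 1 gene, MYO18A (adjusted p 0.0441), and the number over the list alone, 1 with all libraries, was 22 without shGFP, 15 without shEED.2 and 4 without shEED.5. With factors from the ERCC reads the BNIP3 adjusted p over the list was 0.174, at a log2 fold change of 1.99.

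The SUZ12 hairpins were set against control last. RELB, a subunit of NF-kB that acts in its non-canonical pathway, measured 122 ± 10.7 (SD, n = 2) in the shSUZ12 libraries and 590 ± 233 (SD, n = 2) in controls, a log2 fold change of -2.21 (SE 0.35). PTP4A3, a phosphatase, measured 9.72 ± 2.96 and 105 ± 39.4 (log2 fold change -3.28, SE 0.46), and NT5M 675 ± 75.8 and 2278 ± 451 (-1.74, SE 0.24). KIRREL, a cell adhesion molecule, measured 1780.3 and 1855 in the shSUZ12 libraries and 718 ± 203 (SD, n = 2) in controls (log2 fold change 1.37, SE 0.27), WASF1, an actin regulator, 1323 ± 320 and 484 ± 127 (1.45, SE 0.33), and PRPF4B 7689 ± 110 and 4117 ± 258 (0.90, SE 0.20). Over all genes limma called 0, with 1565 at an unadjusted p under 0.05 where chance gives 862, and a smallest adjusted p of 0.0989, for PTP4A3 and NT5M. edgeR called 0 (1504 unadjusted). DESeq2 called 67, 8 higher and 59 lower (1673 unadjusted), among them NT5M, RELB, PTP4A3, KIRREL and WASF1. On 20 other ways to pair the 8 libraries into groups, 10 gave at least 1 of 6 contrasts in which DESeq2 called at least as many. Over all 120 contrasts 28 did, with a median of 4 calls per contrast. Some of these pairings kept a real group. The shSUZ12 pair stood in those with up to 3487 and up to 230 calls, and the control pair in 1 with up to 124. The count is thus not a clean measure of chance. Without shGFP limma called 2 genes, HIST1H1B and MYO18A.

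The list means did not pass in limma for shSUZ12 against control: -1.18 for erythroid and megakaryocyte genes (adjusted p 0.316), -1.07 for NK and cytotoxic genes (0.421), -0.73 for epithelial and embryonic kidney genes (0.316), -0.40 for MHC class I (0.316) and -0.17 for T-cell identity (0.445). Adjusted over the list alone, 36 members of 16 lists passed in limma for shSUZ12 against control, 6 higher and 30 lower, and 0 over all genes. Of the 18 tested genes of MHC class I presentation, 6 fell and 1 rose. HLA-B, a class I heavy chain, measured 2669 ± 653 (SD, n = 2) in the shSUZ12 libraries and 6898 ± 3238 (SD, n = 2) in controls, a log2 fold change of -1.31 (SE 0.34, adjusted p 0.0206). HLA-E fell by 0.93 on the log2 scale (SE 0.21, adjusted p 0.0137) and HLA-C fell by 0.78 (0.0419). The immunoproteasome genes PSMB9 and PSMB10 fell by 0.84 and by 0.67, while ERAP1, which trims peptides for class I molecules, rose by 0.64 (0.0419 for each). HLA class I genes are near-identical, and reads may have been split between them.

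Of the T-cell identity genes, 3 of 32 fell: RUNX3, a repressor of CD4 in cytotoxic cells (log2 fold change -1.51, SE 0.38), CD28, a costimulatory receptor (-1.65, SE 0.41), and GATA3, a regulator of T-cell development (-1.03, SE 0.26), each with a limma adjusted p of 0.0188 over the list alone. Of the leukaemia transcription factors, 3 of 12 fell: LMO2 (-0.93), HHEX (-1.71) and NKX2-5 (-0.81), the last a homeobox gene at 13069 ± 1024 (SD, n = 2) and 23540 ± 8074 (SD, n = 2) in controls. CHI3L2, on the immature thymocyte list, fell by 1.76 on the log2 scale (SE 0.37, adjusted p 0.00943). NOTCH1 targets went both ways. IL7R, the interleukin 7 receptor, rose from 394 ± 146 to 1762 ± 563 (log2 fold change 2.17, SE 0.58, adjusted p 0.0233) and NOTCH3 from 597 ± 296 to 2426 ± 1736 (1.90, SE 0.48, 0.0233), while the transcriptional repressor HES1 fell by 0.86 (0.0474). RELB (adjusted p 7.9e-04) and the activation marker CD83 (-1.06, 0.0230) fell among NF-kB targets. JUND (-1.36), ATF3 (-1.91) and IER2 (-1.21) fell among immediate early genes. IFITM2 (-1.36) and ISG20 (-1.61) fell among interferon-stimulated genes, and CTSW (-1.28), CCL5 (-3.08) and NKG7 (-1.23) among cytotoxic genes. HSPA8 (1.02) and its cochaperone DNAJA1 (0.63) rose among heat shock proteins. PDLIM1, CSF3R, CEBPE, POU2AF1, KRT8 and ITGB7 also fell, and CIITA rose. Of the 36, 1 remained past the threshold without shLuc (RELB, adjusted p 0.0223), 5 without shSUZ12.3, 9 without shSUZ12.2 and 21 without shGFP, and leaving out a library also leaves its group with 1. No fold changed direction, but the genes were chosen by their p in these same libraries. Some kept most of their size in each of the 8 settings: -1.94 to -1.48 for POU2AF1, -2.11 to -1.60 for KRT8 and -1.03 to -0.83 for HLA-E. Others ranged widely: -5.12 to -1.49 for CSF3R, -4.38 to -1.78 for CCL5 and -1.16 to -0.45 for NKX2-5. In the shSUZ12 libraries CSF3R measured 11.4 and 0, and CCL5 5.08 and 0, near the floor. The number passing, other genes included, was 1 without shLuc, 11 without shSUZ12.3, 26 without shSUZ12.2, 55 without shGFP, 58 without shEED.2 and 57 without shEED.5. With factors from the ERCC reads, which moved the median log2 fold change of all genes to 0.34, 4 of the 36 passed and none changed direction.

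**Figure D4:**
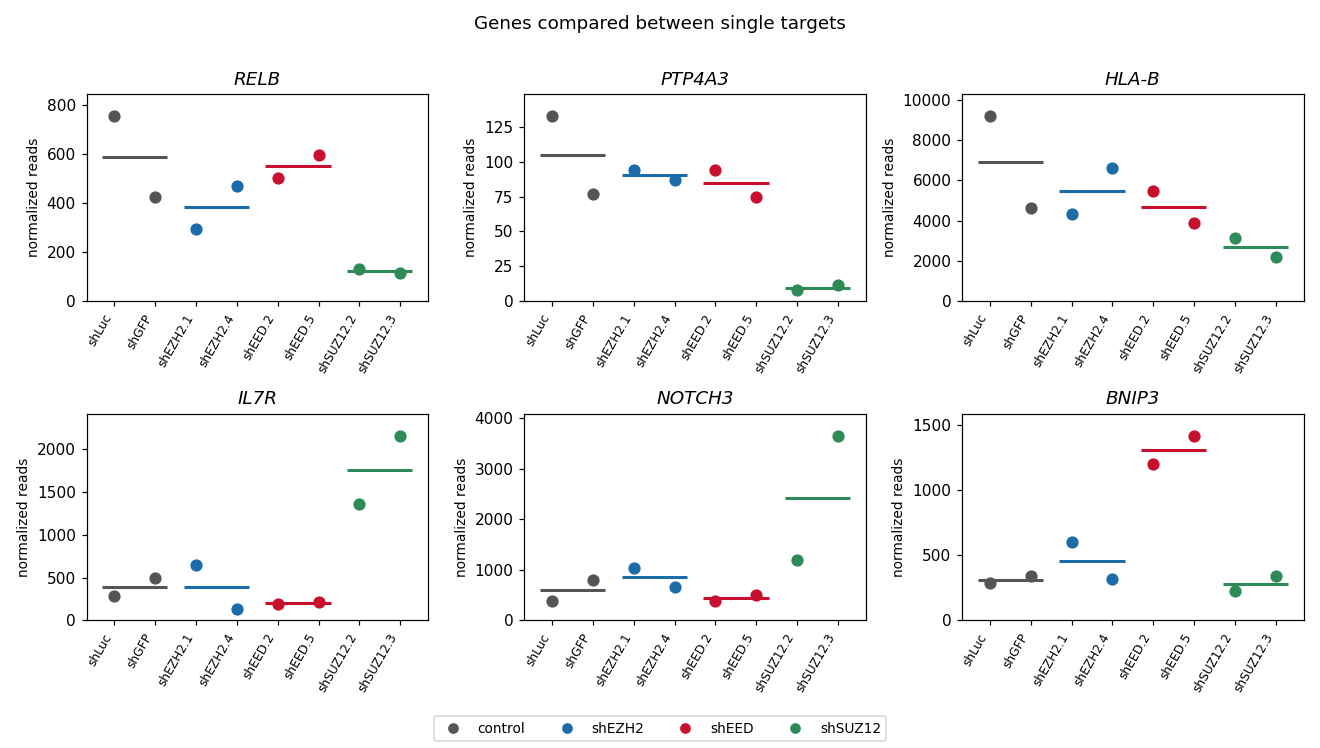
Normalized reads (vertical axes, from 0) of RELB, PTP4A3, HLA-B, IL7R, NOTCH3 and BNIP3 in each of the 8 libraries (horizontal axis); points are libraries and bars are group means. RELB, PTP4A3 and HLA-B are lowest and IL7R and NOTCH3 highest in the 2 shSUZ12 libraries, and BNIP3 is highest in the 2 shEED libraries at 1204 and 1417; with all 8 libraries PTP4A3 passed no threshold in limma and the others passed only over their list alone.

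Targets were also set against each other, in fold changes that use no control value, although the controls enter the shared estimate of the spread. Between shEED and shEZH2, each targeted gene differed in its own direction: EZH2 was higher in the shEED libraries (log2 fold change 1.11, SE 0.21) and EED lower (-1.13, SE 0.23). BNIP3 was higher with shEED (1.59, SE 0.35). These 3 genes passed in limma when adjusted over the list alone (adjusted p 0.00208, 0.00208 and 0.0104), as many without shLuc as with it, while 14 passed without shEZH2.4, 7 without shEED.2 and 5 without shEZH2.1. The BNIP3 call was lost without shEZH2.4 (0.159) or shEED.5. On ERCC factors 0 of the 3 passed (adjusted p 0.659 for EZH2, 0.624 for EED and 0.847 for BNIP3), and 2 other members did. The log2 fold changes were then 0.64 for EZH2, -1.61 for EED and 1.11 for BNIP3, with the median of all genes moved to -0.48. DLGAP3 (-1.56) and ARHGEF16 (-2.51) were lower, neither past the threshold. Over all genes limma called 0 (227 at an unadjusted p under 0.05), edgeR 0 (239) and DESeq2 0 (296). Without shEED.5 limma called 1, KLF2 (adjusted p 0.0348), which measured 1236 in shEED.2 and 142 in shEED.5.

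Between shSUZ12 and shEZH2, IL7R was higher with shSUZ12 (log2 fold change 2.55, SE 0.58), as were EZH2 (1.10, SE 0.21) and SIPA1L2 (1.60, SE 0.38). PTP4A3 (-3.12, SE 0.46) and CDHR1, a cadherin-related gene (-2.44, SE 0.45), were lower, and GAL3ST2 was listed at 0 in both shSUZ12 libraries against 22.4 ± 2.66 (SD, n = 2). Adjusted over the list alone, 9 members passed in limma: EZH2 and IL7R rose, while CDKN1A and CDKN2D, inhibitors of cyclin-dependent kinases, RELB, JUND, SCG2, NKG7 and CCL5 fell. Of these, EZH2 passed without each library in turn (adjusted p up to 0.0450), and 7 of the 9 passed without shLuc or without shGFP, NKG7 and CCL5 being lost. The number passing was 2 without shEZH2.4, 40 without shEZH2.1, 24 without shEED.2, 23 without shEED.5, 16 without shSUZ12.2 and 5 without shSUZ12.3. On ERCC factors 4 passed, among them 3 of the 9 (IL7R, CDKN1A and CCL5), while EZH2 did not (adjusted p 0.955, at a log2 fold change of 1.05). Over all genes limma called 0 (709 at an unadjusted p under 0.05), edgeR 0 (686) and DESeq2 12, 3 higher and 9 lower (781). Without shEZH2.1 limma called 1, IL7R (adjusted p 0.0118).

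Lastly shSUZ12 was set against shEED. IL7R was higher with shSUZ12 (log2 fold change 3.08, SE 0.58), as were KIRREL (1.40, SE 0.27) and EED (1.13, SE 0.23), and CDHR1 (-3.39, SE 0.45), PTP4A3 (-3.02, SE 0.46) and BNIP3 (-2.23, SE 0.35) were lower. Adjusted over the list alone, 23 members passed in limma, 12 higher and 11 lower. Among them 6 of 13 genes encoded by the mitochondrial genome rose, from 0.46 for MT-CO1 to 0.81 for MT-ATP8, with MT-ND5 at 17916 ± 485 (SD, n = 2) and 10339 ± 372 (SD, n = 2). IL7R (adjusted p 0.00300), NOTCH3 (0.00521), EED, ERAP1, ID2 and HIST1H2AC also rose. RELB (9.7e-04), NFKB2, BNIP3 (5.2e-04), CDKN1A, CDKN3, CDKN2D, PDLIM1, CCL5, HLA-E, SLC16A3, a lactate transporter, and FZD2 fell. Over the NOTCH1 target, NF-kB target and BCL2 family lists, IL7R, RELB and BNIP3 passed without each library in turn, with adjusted p of up to 0.0491, 0.0144 and 0.0130, though IL7R did not over the JAK-STAT list without shSUZ12.3 (0.0693). On ERCC factors, which moved the median log2 fold change of all genes to 0.43, 7 of the 23 remained among 10 that passed. IL7R still passed over the NOTCH1 target list (adjusted p 9.0e-05), while RELB (0.480) and BNIP3 (0.339) did not. The log2 fold changes were then -1.73 for RELB and -1.80 for BNIP3. The 6 mitochondrial calls were lost without shEED.2, shSUZ12.2 or shSUZ12.3. They were also lost with ERCC factors (adjusted p 0.219 to 0.232), though the log2 fold changes were then larger, from 0.89 for MT-CO1 to 1.25 for MT-ATP8. The calls of ERAP1 and HLA-E were lost without any 1 of the 8 libraries. Without shLuc or without shGFP 18 of the 23 remained, CDKN1A, HIST1H2AC and FZD2 also being lost. Of the 23, 5 remained without shSUZ12.3, 7 without shSUZ12.2, 11 without shEED.2 and 13 without shEED.5. The number passing, other genes included, was 6 without shSUZ12.3 and 35 without shEZH2.1, shEED.2 or shEED.5. Over all genes limma called 0 (1413 at an unadjusted p under 0.05), edgeR 0 (1339) and DESeq2 41, 12 higher and 29 lower (1523). Without shEZH2.1 or without shEZH2.4 limma called 3: IL7R, CDHR1 and BNIP3.

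Whether the targets shared a response was asked by comparing their log2 fold changes against control across the 17239 genes, which are not independent replicates. The correlation between shEZH2 and shEED was 0.517 (covariance 0.121), against 0.501 (0.138) simulated for unchanged groups with the same controls. Between shEZH2 and shSUZ12 it was 0.549 (0.172), against 0.493 (0.138), and between shEED and shSUZ12 it was 0.392 (0.135), against 0.491 (0.138). The covariance thus differed from the simulated one by -0.0166, 0.0344 and -0.00353, and part of any excess may come from the shared controls, which cannot be split further than 1 library each. Without shGFP the correlations were 0.770, 0.781 and 0.689. Without shEED.5 the first and the third were 0.282 and 0.196.

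On average over the 3 targets, the 2 hairpins for 1 target did not resemble each other more than hairpins for different targets. Deviations from the mean of the 6 knockdown libraries had a mean correlation across genes of -0.208 over the 3 same-target pairs, which 9 of the 15 possible pairings reached (exact one-sided p 0.6, where 0.0667 is the smallest possible). The highest correlation of any pair of libraries was 0.190, between shEZH2.4 and shEED.5. The shSUZ12 libraries had -0.095, the shEED libraries -0.254 and the shEZH2 libraries -0.275. Deviations from a shared mean tend to correlate negatively, so a negative value is not in itself a sign of dissimilarity. The pairing with the highest mean correlation (0.0288) held the shSUZ12 pair but neither the shEED nor the shEZH2 pair. The first principal component held 28.4% of the variance and placed shLuc (-63.7) and shEED.2 (-44.5) opposite shSUZ12.2 (56.8) and shSUZ12.3 (40.4). In shLuc and shEED.2, ERCC reads made up 12.9% and 11.3% of reads, the highest shares of the 8 libraries. Each library's deviations from the gene means over the 8 libraries were also set against length and GC content of transcripts. These accounted for 14.2% and 9.65% of the variance of the deviations in shLuc and shEED.2, against 1.41% to 6.81% in the other 6.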

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

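The S phase test and the untailed genes by level were tests chosen after the result was seen. An outlying library was sought in 151 sets of values, and 7 met the rule that the gap to the nearest library be a large share of the range, where chance marks about 1 in 20 (7.55 expected). Adjusted over all genes, no gene differed between targets at the threshold of limma, with unadjusted counts, other tools and the members passing over the list alone as given for each contrast in the report.

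Histone genes listed as lacking poly(A) tails stood apart in shLuc, though whether each member's transcripts lack tails was not measured. shLuc held 0.0227% of its gene reads in them, against 0.00391% to 0.00727% in the other libraries. The gap was 0.821 of the range, and 0.836 of the range for the list mean. The 16 members were a median of 1.85 (log2) above the mean of the other 7 libraries, and 16 of 16 were above that mean, though HIST1H2AC, HIST1H2BK and HIST1H2BD were higher still in at least 1 knockdown library. A gain of reads shared by all short transcripts is argued against as the whole cause. The 1386 non-histone genes with transcripts in the range of the histone genes, 312 to 1668 bases, were a median of 0.44 higher (interval 0.41 to 0.47). Lengths were not matched within that range, so a larger gain of the shortest transcripts was not tested. More RNA without poly(A) tails in shLuc may contribute but cannot be told apart, since 126 such genes were a median of 0.19 higher with an interval of -0.00130 to 0.38, and only 38 of them had a mean of at least 20 in the other 7 libraries. The 5 with a mean of at least 100 were all higher, by a median of 0.83, among them RN7SK (771 against 62.3 to 234, 2.32). Of the 9 with at least 50, 7 were higher, while SNORD17 (-1.84) and SNORA73B (-0.71) were lower, and RPPH1, below that level, was higher (2.22). More cells in S phase cannot be told apart either, since the DNA replication list was 0.0466 higher with an interval of -0.06 to 0.11, and no other biological explanation was tested.

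HHLA3 was low in shSUZ12.3 at 134.6, against 180.8 to 213.7 in the other 5 knockdown libraries, a gap of 0.638 of the range. HSPD1 was high in shSUZ12.2 at 43732, against 30366 to 34682 (0.636). NCL was high in shSUZ12.2 at 92229.9, against 71547 to 75372 (0.795). SLC25A5 was low in shSUZ12.2 at 20492, against 26243 to 30014 (0.648). CSF3R was listed at 0 in shSUZ12.3, against 10.1 to 32.1 (0.687).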

How the results depend on the processing

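Chosen after the data were seen were edgeR with TMM factors, limma with library size only, the removal of length and GC trends, leaving out shLuc and shEED.2 together, and, for lists, log2 CPM, ERCC factors and pseudocount 0.1. Of 2536 values of named genes and lists under an alternative, 2367 kept direction and side of the threshold. No longer past it were 75, while 45 came past it (37 of them with DESeq2) and 49 changed sign (32 without 1 library). The cause was not tested. For genes the threshold was that over all genes, which none had passed in the main test, so no gene could fall out. The 75 were therefore values of lists. Calls over the list alone were not counted here, so the share that kept its side does not describe them. No paired analysis was possible because the numbers name hairpins, not matched samples, and controls carry none. A group left with 1 library was assumed to vary like the others. Counting error was not measured apart for genes near the minimum value of 10, and whether depth limits the calls there was not tested.

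With DESeq2, calls numbered 1 for shEED against control, 67 for shSUZ12 against control, 12 for shSUZ12 against shEZH2 and 41 for shSUZ12 against shEED, where limma called 0, and ERCC factors gave 2 for shSUZ12 against shEZH2. Without 1 library limma called 0 to 5 genes for knockdown against control, 0 to 1 for shEED and 0 to 2 for shSUZ12 against control, 0 to 1 for shEED and for shSUZ12 against shEZH2, and 0 to 3 for shSUZ12 against shEED. Lists passing camera, 11 as reported, numbered 3 with no filter on low values, 5 without shLuc and shEED.2, 0 with an estimated correlation, 0 by fry and 5 to 13 without 1 library.

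Correlations between targets (shEZH2 with shEED, shEZH2 with shSUZ12, shEED with shSUZ12) were 0.487, 0.524 and 0.365 with a pseudocount of 0.25, and 0.498, 0.517 and 0.374 with trends removed. Among genes above the median level the first 2 were 0.589 and 0.651. Without 1 library they ranged from 0.282 to 0.770, 0.410 to 0.781 and 0.196 to 0.689.

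Without shLuc and shEED.2, lists changed sign to 0.17 for histone genes, 0.069 for ribosomal proteins, 0.13 for mitochondrially encoded genes and 0.16 for oxidative phosphorylation. Without 1 library these ranged from -2.15 to 0.21, -0.33 to 0.15, -0.50 to 0.12 and -0.38 to 0.21, and HOX genes from -0.26 to 0.0329.

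With ERCC factors, which moved the median of all genes by 0.22 in the comparison of knockdown with control, log2 fold changes changed sign to 0.19 for ATP5A1, 0.20 for CALR, 0.055 for EZH2, 0.17 for IRX3, 0.22 for LDHA, 0.0235 for MT-CO1, 0.16 for PAX6, 0.0802 for RPS4X and 0.11 for SLC25A5. IRX3 was 0.0131 with DESeq2, 0.0101 with RLE factors and 9.6e-04 with TMM factors, and LDHA was 0.00262 with DESeq2. Without 1 library the ranges were -0.19 to 0.12 for ATP5A1, -0.0270 to 0.12 for ATP5B, -0.61 to 0.0257 for B2M, -0.26 to 0.20 for CALR, -0.0948 to 0.27 for EED, -0.37 to 0.0223 for EZH2, -1.73 to 0.44 for HIST1H1C, -0.86 to 0.24 for IFITM1, -0.18 to 0.12 for IRX3, -0.11 to 0.77 for KDM5C, -0.0799 to 0.0326 for LDHA, -0.70 to 0.00338 for MT-CO3, -0.17 to 0.0304 for PAX6, -0.40 to 0.10 for RPS4X, -0.29 to 0.0428 for SLC25A5, -0.23 to 0.32 for SUZ12 and -0.0896 to 0.40 for WHSC1.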

Other observations

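The calls without both shLuc and shEED.2, and the implanted changes and residual SD without shLuc, were tests of this part chosen after the result was seen. In the comparison of knockdown with control limma called 0 genes, with 508 at an unadjusted p under 0.05, edgeR 0 (537) and DESeq2 0 (656). Other splits of the libraries into 2 and 6 decide nothing about chance here: with a real count of 0, 28 of the 28 splits must give as many, the highest other being 1018 with shLuc and shEED.2 as the pair. A split with so many calls points to a structure of the samples that does not follow the targets, though 1 target pair also gave calls. The 2 shSUZ12 libraries against the other 6 gave 4 calls and 2856 separated genes. Calls also came from shEZH2.1 with shSUZ12.3 (31) and from shEZH2.4 with shEED.5 (1). The shEZH2 pair and the shEED pair gave 0.

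Several explanations for the lack of calls were tested. Whether the shLuc library alone widens the spread stays open. limma called 0 genes without it (111 at an unadjusted p under 0.05), but this leaves 1 control, and 0.025% of implanted 2-fold changes and 85.1% of 4-fold ones were then called. The median residual SD was 0.337 without shLuc and 0.345 with all libraries. Leaving out both shLuc and shEED.2, with 0 calls (159), also leaves 1 control. Removing library-wide trends with transcript length and GC content brought no gene past the threshold. Afterwards limma called 0 genes, with 513 at an unadjusted p under 0.05, against 386 before on the same 14505 genes. The removal lowered the median residual SD by 12.1%. Recovery of implanted changes was not measured after it, so whether the trends hide smaller changes stays open. Too little power for large changes is argued against only for genes with a mean of at least 100, from which the changed genes were drawn. There 97.4% of simulated 4-fold changes were called (96.1% when implanted in the real libraries). Of 2-fold changes 52.4% were called (41.3% when implanted), so smaller changes may have been missed. Power for genes below that mean was not measured. A weak effect of the incomplete knockdown was not tested.

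TRAP1 was higher in 6 of 6 knockdown libraries than in both controls, with a log2 fold change of 0.57 (0.34 without shLuc) and a limma adjusted p of 0.948, from 0.279 to 1.00 without 1 library. Chance may account for such a gene, since 17 of the 28 splits gave as many separated genes as the real 852, the highest other being 4506. Trends with transcript length and GC content are argued against, since the log2 difference was 0.70 after their removal (122% of the uncorrected value) with 6 of 6 libraries still above both controls. A response to loss of PRC2 stays open, and the study chose this gene from these samples.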
